A study of Mus musculus with 6 samples.

How the data were processed

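Sequencing libraries were made from total RNA of L1CAM+ thymic tuft cells sorted into SMART-seq lysis buffer, per the labels' protocols. The 6 samples form 2 groups of 3, Foxn1-Cre-negative and Foxn1-Cre-positive mice with floxed Ikzf1. Per the submitters' processing notes the authors used STAR 2.7.9a, the genome build GRCm39 and DESeq2, whose version was not given; the read counter, the annotation release, strandedness and filters are not given in the sources used here. The deposited expression values are a signal, gene counts divided by 1 size factor per library. The authors' deposited comparison table holds a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value per gene, per the file headers, and the mean signal of the 6 libraries. Its fold changes have the sign of Ko over Het for 99.9% of genes with a mean of at least 50. Adjusted p-values left blank there (NA) were kept as NA.

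The columns are named Het1 to Het3 and Ko1 to Ko3. Ko was matched to the genotype given as KO, and Het to the remaining genotype, given as WT, by elimination. The columns could not be tied to single samples. The table holds 55471 genes by Ensembl identifier. Symbols came from a gene name table, which matched 55144 of them and 19390 of the 19416 tested, and older symbols in the lists were looked up in a RefSeq table of GRCm38.p6, a build other than the authors', so no coordinates are given.

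Each column's values were whole multiples of what 1 read is worth there. Dividing by this step gave whole numbers, within 0.01 reads, for 100% of values above 0, and those reads gave library totals of 12238400 to 31435800, to 6 digits. In the least deep libraries, Het3 and Ko3, 3 reads correspond to normalized values of 4.33 and 4.30. Differences in counts between replicates exceeded sampling noise in all 6 pairs within groups (chi-square per degree of freedom 58.0 to 147), so no library was a second copy of another in its group. Pairs across the groups were not checked in this way.

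Genes with a mean normalized value of at least 10 over the 6 libraries were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. With 3 libraries against 3, an exact permutation test of a single gene could not go below 0.10, so limma's shared variance estimate was used. For genes with 1 to 3 reads in a group, the ratio of rates and its 95% interval were computed from reads, and for 0 reads a floor of 3 reads over the group was used.

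The 36 gene lists, for tuft cells, other thymic epithelial and mimetic cells, signalling, chromatin and contaminating cells, were fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma (two-sided, preset inter-gene correlation 0.01, adjusted over the lists), with an estimated correlation and with fry. Estimating the correlation also leaves camera only the few residual degrees of freedom of the 6 libraries. A call lost in that setting therefore need not come from correlated genes. Ribosomal protein genes were taken by symbol, leaving out pseudogenes, kinases and other genes that share the symbol start; the Tas2r list includes genes named as pseudogenes. Genes were named by a rule also fixed before: Ikzf1 to Ikzf5 and L1cam; among called genes with a mean of at least 50 and no overlap between groups, the 12 largest log2 fold changes in each direction, counting but not naming genes without a conventional symbol, which were 15 of the 158 called; and up to 4 members of each list with the smallest p. Genes given outside this rule, in the closing section, were chosen after their values were seen.

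The tests were checked on 5 simulated data sets with the real means, depths and dispersions, and 19416 genes. Changed genes were drawn only from genes with a mean of at least 50, so the recovery of lower genes was not measured. Limma recovered 5.97% of genes changed 2-fold, 40.0% of those changed 4-fold and 55.2% of those changed 8-fold, with 32 calls among 96080 unchanged gene tests. Camera called 0 of 180 unchanged lists and the moved list in 5 of 5 simulations. Genes were drawn independently there, so this says nothing about false list calls among correlated genes. Alternatives fixed beforehand were other pseudocounts (0.5, 5 and 20), no filter or a mean of at least 50, TMM, equal-total and quantile scaling, robust eBayes, array weights, edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and voom on the recovered reads, and leaving out each library. Chosen after the data were seen were a block by column number, thinning all libraries to the reads of the smallest, list tests under the other scalings, and edgeR and DESeq2 without each library.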

Results

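RNA was measured by sequencing in thymic tuft cells, chemosensory epithelial cells of the mouse thymus that were sorted on the surface marker L1CAM. Both genotypes carried floxed alleles of Ikzf1, the gene for the zinc finger transcription factor Ikaros, and were either negative or positive for Foxn1-Cre, a recombinase expressed in thymic epithelium. The labels describe 3 Cre-negative samples, given as WT, and 3 Cre-positive samples, given as KO. The columns of the expression table are named Het1 to Het3 and Ko1 to Ko3; the Ko columns were read as the Cre-positive group, and the Het columns as the Cre-negative group by elimination, since no label uses that word. Recovered whole-read totals were 31435800, 25210600 and 12429300 for Het1, Het2 and Het3, and 16775000, 17140800 and 12238400 for Ko1, Ko2 and Ko3, each to 6 digits. Between 26727 and 35130 genes had at least 1 read in a library. Mitochondrial genes took 8.66% to 11.1% of reads in Het libraries and 10.4% to 12.1% in Ko libraries, and ribosomal protein genes took 2.49% to 2.53% and 3.07% to 3.31%. Pearson's r across genes, which are not independent replicates, was 0.781 to 0.790 among Het libraries, 0.829 to 0.837 among Ko libraries and 0.738 to 0.815 between the groups. Het1 correlated more with the Ko libraries (0.801 to 0.815) than with Het2 (0.790) or Het3 (0.787). On the first principal component, with 31.4% of the variance, it lay at -25.0, Het2 and Het3 at -119 and -155, and the Ko libraries at 84.3 to 125. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these samples, which may be in part technical.

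The targeted gene was examined first. Ikzf1 (ENSMUSG00000018654) was higher in the libraries labelled Ko, at 254 ± 59.7 normalized counts in Het libraries and 1584 ± 128 in Ko libraries (SD, n = 3 each), a 6.34-fold difference. Its values were 301, 187 and 273 in Het1, Het2 and Het3 and 1572, 1463 and 1717 in Ko1, Ko2 and Ko3, resting on 991 and 4139 reads. The log2 fold change was 2.66 ± 0.30 (SE; limma adjusted p = 0.0105), and the call was lost without Het3 (adjusted p = 0.0621; over 21 alternatives the adjusted p ran from 3.16e-14 to 0.0621). This direction goes against a loss of Ikzf1 RNA in the Ko group. The labels do not give the deleted part of the gene, and a count over the whole gene does not show whether that part was missing. Every direction below is therefore between libraries as they are labelled, not between verified genotypes. No other Ikaros family member passed the test. Ikzf3 stood at 288 ± 128 in Het and 81.2 ± 68.9 in Ko libraries (limma adjusted p = 0.309), Ikzf4 at 258 ± 151 and 476 ± 98.9 (0.383), Ikzf2 at 487 ± 223 and 402 ± 38.2 (0.891), and Ikzf5 at 297 ± 31.7 and 329 ± 36.2 (0.905; SD, n = 3 each). The sort marker L1cam was at 2745 ± 331 and 3670 ± 687, a difference that did not pass the test (limma adjusted p = 0.408).

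The design asks which genes differ in tuft cells between the 2 genotypes. In the libraries labelled Ko, 56 genes were higher and 102 lower of 19416 tested (limma, adjusted p under 0.05). Among the largest rises, 4 genes were close to undetected in Het libraries and present in every Ko library. Fxyd7, a regulator of the sodium pump, rose from 0.846 ± 0.748 to 472 ± 40.5 normalized counts, and Fcna, encoding ficolin A, from 3.33 ± 2.22 to 257 ± 120. Gabrg3, a GABA-A receptor subunit, rose from 7.67 ± 5.55 to 252 ± 34.8, and the homeobox gene Hoxa2 from 6.14 ± 3.56 to 214 ± 25.2. Stmn2, encoding the microtubule regulator stathmin-2, was low but detected in Het libraries and rose from 62.8 ± 47.8 to 1318 ± 354. The log2 fold changes of these 5 genes were 8.10 ± 1.01, 5.90 ± 1.04, 5.18 ± 0.99, 5.03 ± 0.94 and 4.78 ± 0.71 (SE). Moderate levels in Het libraries were set against 5.29- to 7.56-fold higher levels in Ko libraries for Ank2 (log2 fold change 2.92), Barx1 (2.66), Ccnj (2.46), Lrmda (2.46), Rbpjl (2.45) and the semaphorin receptor gene Plxna4 (2.40). Limma adjusted p-values of these 11 genes lay between 0.0122 and 0.0491, and DESeq2 called all of them. Of the 11, edgeR called only Fxyd7, Fcna and Stmn2 (edgeR adjusted p = 0.0178, 0.0441 and 0.0484). The remaining genes lay between 0.0532 and 0.114 in edgeR. Voom called none of the 11, with the lowest voom adjusted p, 0.0501, for Stmn2.

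Genes lower in the libraries labelled Ko included many that were almost unread there. Klk1b26, a tissue kallikrein, had 1778 reads in Het and 1 in Ko libraries, a ratio of normalized rates of 1205 with a 95% counting interval from 216 to 47608. Sntn, a gene of motile cilia, had 3892 and 3 reads (ratio 879, interval 301 to 4264), Fabp7 1436 and 2 (486, 134 to 4021) and Sycn 670 and 1 (454, 81.2 to 17956), with 825 and 1 reads for Cdhr4. Gkn1, encoding the stomach protein gastrokine 1, had 623 and 0 reads and was at least 141-fold lower, and Sprr2e, a cornified envelope gene, had 922 and 0 reads and was at least 208-fold lower, with a floor of 3 reads over the group. These intervals and floors cover counting error only. The log2 fold change was -7.34 ± 0.99 for AU040972, -7.30 ± 0.86 for the uroplakin gene Upk3a, -7.27 ± 1.07 for the small GTPase gene Arl14, -7.16 ± 1.16 for the chitinase-like gene Chil4 and -7.12 ± 1.01 for the keratin gene Krt6b (SE). Limma adjusted p-values of these 12 genes lay between 0.0111 and 0.0403, and DESeq2 called all of them. Of the 12, edgeR did not call Sprr2e, Gkn1, AU040972 or Cdhr4 (edgeR adjusted p = 0.0773, 0.0592, 0.0533 and 0.0523). Voom called none of the 12, with voom adjusted p-values from 0.0902 for Arl14 to 0.591 for Sntn. Klk1b26 and Sprr2e belong to families of near-identical genes, so their separate values are uncertain.

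Each of the 158 called genes had groups that did not overlap, which follows largely from their selection by a small p. Over all tested genes that share was 18.4%, against 10% expected by chance, and 2644 genes had an unadjusted p under 0.05. The authors' deposited table gave 599 genes as higher and 1018 as lower at adjusted p under 0.05, and all 158 were among them in the same direction. The size of the call set rested on single libraries: limma called 106 genes without Het1, 14 without Het2, 0 without Het3, 116 without Ko1, 56 without Ko2 and 50 without Ko3. Without Het3, 2080 genes had an unadjusted p under 0.05, all 158 among them, while edgeR called 0 and DESeq2 873. The 158 were picked in a test that included the remaining libraries, so their staying under 0.05 was largely fixed by that choice. The loss in edgeR was not particular to Het3, since edgeR called 120, 6, 3, 1 and 0 genes without Het1, Het2, Ko1, Ko2 and Ko3. DESeq2 called 878 to 1529 genes without these libraries. The dependence on single libraries limits every single gene called here. With all 6 libraries edgeR called 24 higher and 51 lower, voom 20 and 20, and DESeq2 383 and 768; rescaling with TMM factors gave 37 and 127, so that 22.6% of calls were higher in place of 35.4%.

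**Figure D1:**
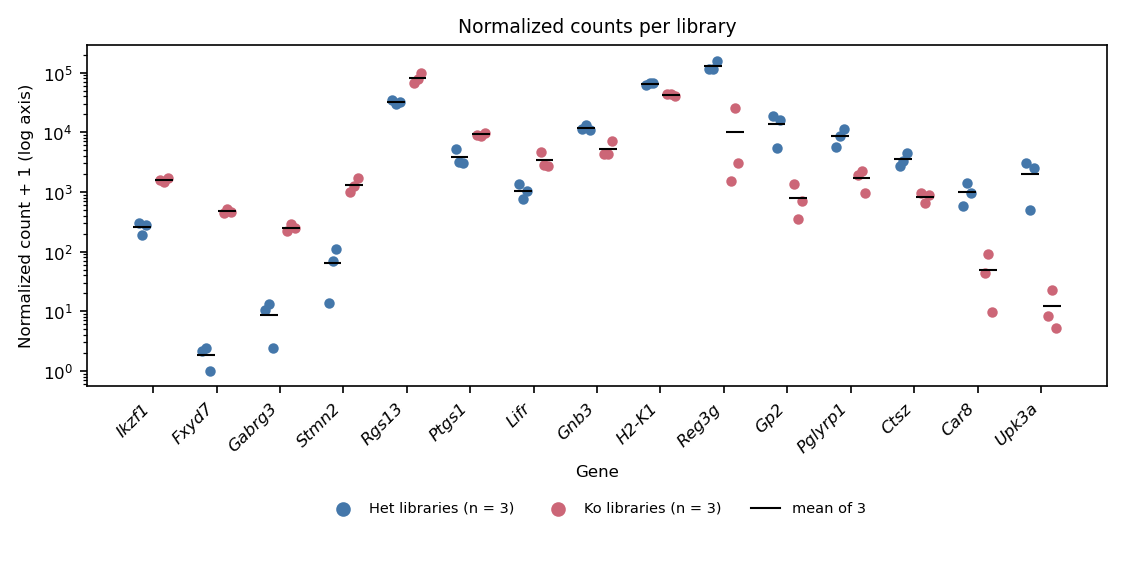
Normalized counts plus 1 (log axis) of 15 genes in each of the 3 Het and 3 Ko libraries; points are libraries and bars are means of 3. Ikzf1 lies between 1463 and 1717 in the libraries labelled Ko and between 187 and 301 in the Het libraries. The groups do not overlap for any gene shown, which follows largely from the choice of genes called by limma. Over all tested genes that share was 18.4%.

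Transcripts that define tuft cells were abundant in all 6 libraries. Of 46 tested members of the tuft cell identity list, 35 had a positive and 11 a negative fold change, with a median log2 fold change of 0.34; 2 rose and 0 fell over all genes tested, and 4 rose and 2 fell adjusted over the list alone. The list passed camera as higher in the libraries labelled Ko (adjusted p = 4.59e-05), but not with an estimated correlation (adjusted p = 0.547). Its mean log2 level overlapped between groups, at 12.39, 12.02 and 11.86 in Het1, Het2 and Het3 and 12.30, 12.26 and 12.48 in Ko1, Ko2 and Ko3. Its median log2 fold change was 0.16 without Het3. The list took 2.98%, 2.43% and 2.14% of reads in Het1, Het2 and Het3 and 2.99%, 2.99% and 3.44% in Ko1, Ko2 and Ko3. In mean log2 level, a different measure, 14 of 18 lists of other cells were lower in the Ko libraries. The 18 leave out the secretory list, which also fell. Shares of reads of these lists went both ways. Aire-stage genes took 0.221%, 0.462% and 0.579% in Het1, Het2 and Het3 and 0.151%, 0.151% and 0.129% in Ko1, Ko2 and Ko3. B cell genes took 0.0239%, 0.0162% and 0.0241% in Het1, Het2 and Het3 and 0.0330%, 0.0389% and 0.0392% in Ko1, Ko2 and Ko3. Rgs13, encoding a regulator of G protein signalling, rose from 32005 ± 2645 to 81568 ± 15215 normalized counts (SD, n = 3 each; limma adjusted p = 0.00868). Ptgs1, encoding cyclooxygenase-1, rose from 3813 ± 1149 to 9203 ± 645 (limma adjusted p = 0.0264). The prostaglandin D synthase gene Hpgds was at 4442 ± 280 and 6888 ± 572 (limma adjusted p = 0.0860) and Gng13 at 27672 ± 2147 and 17173 ± 2629 (0.0504). In the taste signal transduction list (16 tested, median -0.61, camera adjusted p = 0.221), Rgs13 rose and the G protein subunit gene Gnb3 fell from 11988 ± 1218 to 5274 ± 1657 (limma adjusted p = 0.0341); adjusted over the list alone, 1 rose and 4 fell. The eicosanoid synthesis list was not called (18 tested, median 0.14, camera adjusted p = 0.0962); Ptgs1 rose, and adjusted over the list alone 3 rose and 2 fell.

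Bitter taste receptor genes passed camera as lower in the libraries labelled Ko (36 Tas2r genes tested, median log2 fold change -1.27, adjusted p = 0.0162; adjusted p = 0.583 with an estimated correlation), with 27 negative and 9 positive fold changes and 0 members called, also adjusted over the list alone. Tas2r105 was at 6814 ± 2188 in Het and 3397 ± 1441 in Ko libraries, while Tas2r108 went the other way, at 1378 ± 415 and 2631 ± 525. The groups overlapped in the list's mean log2 level, which was lowest in Het1, at 5.50, against 8.49 and 7.67 in Het2 and Het3 and 6.48, 6.09 and 5.62 in Ko1, Ko2 and Ko3. The list's call was lost without Het2 (median -0.77, adjusted p = 0.494), Het3 (0.0639), Ko2 (0.0521) or Ko3 (0.0502). It was also lost with genes of a mean of at least 50 (0.0549; over its alternatives the adjusted p ran from 1.76e-05 to 0.583). Tas2r genes are similar in sequence, so reads may be shared among them. Tuft cell cytokines and cytokine receptors were not called (20 tested, median -0.45, camera adjusted p = 0.199; 0 members called, 1 rose and 1 fell adjusted over the list alone).

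Among lists of other medullary epithelial fates, several fell in the libraries labelled Ko, while those of ionocytes, muscle and gut and liver cells were not called. Thymic mimetic cells are medullary epithelial cells that express programs of peripheral tissues. Secretory and goblet-like genes fell with a median log2 fold change of -2.43 (19 tested, 16 negative; camera adjusted p = 2.02e-07; adjusted p = 0.368 with an estimated correlation), 3 members falling over all genes and 10 adjusted over the list alone. Reg3g, an antimicrobial lectin gene, fell from 128750 ± 24061 to 10170.3 ± 13645 normalized counts, Fcgbp from 7374 ± 3603 to 1346 ± 693 and the mucin gene Muc13 from 455 ± 127 to 68.6 ± 18.4 (SD, n = 3 each; limma adjusted p = 0.0341, 0.0408 and 0.0476). Microfold genes fell with a median of -1.14 (16 tested, 11 negative; camera adjusted p = 0.00144; adjusted p = 0.289 with an estimated correlation), 2 members falling over all genes and 6 adjusted over the list alone. Their median was -0.42 without Het1, -0.65 without Ko2 and -0.64 with genes of a mean of at least 50. Gp2, the microfold cell receptor for bacterial pili, fell from 13495 ± 7002 to 801 ± 510 (limma adjusted p = 0.0123) and Pglyrp1, a peptidoglycan recognition protein gene, from 8536 ± 2786 to 1707 ± 674 (0.0190). Ciliated cell genes fell with a median of -1.72 (19 tested, 15 negative; camera adjusted p = 0.00132; adjusted p = 0.403 with an estimated correlation), with 0 members called and 6 lower adjusted over the list alone. Foxj1, the transcription factor gene of motile ciliated cells, was at 261 ± 151 in Het and 26.0 ± 28.0 in Ko libraries. Shares of reads of the ciliated list overlapped between the groups. They were 0.0452%, 0.106% and 0.0616% in Het1, Het2 and Het3 and 0.0472%, 0.0440% and 0.0404% in Ko1, Ko2 and Ko3. The list's call was lost without Het2 (adjusted p = 0.0845; over its alternatives 4.17e-04 to 0.403). Ribosomal protein genes took a larger share of reads in the Ko libraries that were lower for these lists, 3.07% to 3.31% against 2.49% to 2.53%.

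Keratinocyte-like genes fell with a median log2 fold change of -1.38 (20 tested, 14 negative; camera adjusted p = 0.00289; adjusted p = 0.403 with an estimated correlation), with 0 members called and 3 lower adjusted over the list alone. Ko1 showed almost no fall, with a mean log2 level of 9.02 against 9.50, 9.08 and 9.35 in Het1, Het2 and Het3, while Ko2 and Ko3 were at 7.17 and 6.63. Without Ko1 the median was -2.15. Ivl, encoding involucrin, was at 476 ± 567 in Het and 3.43 ± 4.28 in Ko libraries. Neuroendocrine and enteroendocrine genes fell with a median of -1.41 (19 tested, 15 negative; camera adjusted p = 0.0220; adjusted p = 0.368 with an estimated correlation), 2 members falling over all genes, and 1 rising and 2 falling adjusted over the list alone. Car8, a carbonic anhydrase-related gene, fell from 980 ± 427 to 47.3 ± 40.9 (limma adjusted p = 0.0341), and Gip, the gene of an incretin hormone, had 452 reads in Het and 1 in Ko libraries (ratio 306, interval 54.7 to 12122; limma adjusted p = 0.0493). This list's call was lost without Het1 (adjusted p = 0.0666), Het2 (0.0692), Ko1 (0.0547) or Ko3 (0.0676). It was also lost with genes of a mean of at least 50 (0.102; over its alternatives 0.00392 to 0.368). Its median was -2.31 without Het3 and -2.30 without Ko2. The list's share of reads overlapped between the groups. It was 0.0327%, 0.0518% and 0.0452% in Het1, Het2 and Het3 and 0.0367%, 0.0399% and 0.0254% in Ko1, Ko2 and Ko3. Lists of ionocytes (11 tested, median -0.73, camera adjusted p = 0.452), muscle cells (21, 0.44, 0.492) and gut and liver cells (18, -0.91, 0.218) were not called and had 0 called members; adjusted over the list alone, 1 ionocyte gene rose and 2 fell, 1 muscle gene rose and 1 fell, and 0 gut and liver genes were called.

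**Figure D2:**
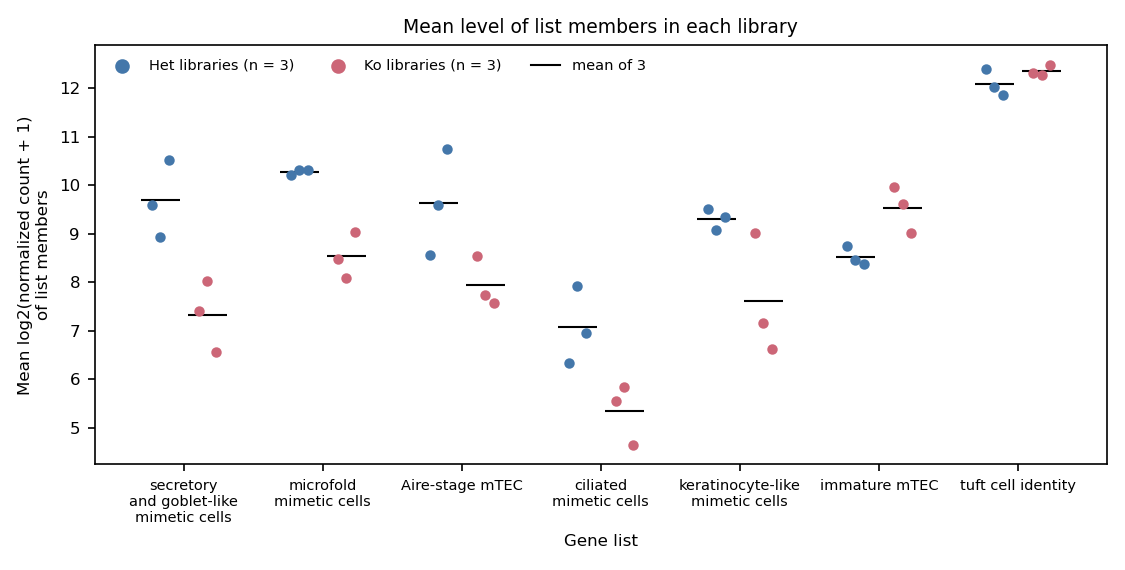
Mean log2(normalized count + 1) over the members of 7 gene lists in each library; points are the 3 Het and 3 Ko libraries and bars are means of 3. The secretory list lies between 8.94 and 10.52 in Het libraries and between 6.56 and 8.04 in Ko libraries, whereas the tuft cell list overlaps between the groups.

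Genes of the Aire stage of medullary thymic epithelial cells (mTEC) also fell, with a median log2 fold change of -1.69 (20 tested, 18 negative; camera adjusted p = 2.92e-06; adjusted p = 0.368 with an estimated correlation), 1 member falling over all genes and 8 adjusted over the list alone. Het1 lay level with Ko1 in the mean log2 level of this list, at 8.57 and 8.53, with Het2 and Het3 at 9.60 and 10.74 and Ko2 and Ko3 at 7.73 and 7.57. Without Het3 the median was -1.08. The called member was Ctsz, a cathepsin gene, at 3506 ± 875 in Het and 833 ± 163 in Ko libraries (SD, n = 3 each; limma adjusted p = 0.0121). The ubiquitin-like gene Ubd was at 28171 ± 17446 and 5494 ± 1707 (limma adjusted p = 0.101). Of the 20 genes, 5 were shared with another list. MHC class II and costimulation genes fell with a median of -0.95 (15 tested, 14 negative; camera adjusted p = 1.92e-05; adjusted p = 0.403 with an estimated correlation), with 0 members called, and 1 higher and 7 lower adjusted over the list alone. Here too Het1 lay near the Ko libraries, at a mean log2 level of 10.11 against 9.70, 9.96 and 9.62 in Ko1, Ko2 and Ko3, with Het2 and Het3 at 11.36 and 11.68. H2-Ab1 was at 39199.5 ± 13678 and 21193 ± 5319, with overlapping groups. MHC class I presentation genes fell with a median of -0.34 (19 tested, 18 negative; camera adjusted p = 2.15e-06; adjusted p = 0.172 with an estimated correlation), 1 member falling over all genes and 6 adjusted over the list alone. H2-K1 fell by 0.62 ± 0.09 on the log2 scale (SE; limma adjusted p = 0.0191), from 65551 ± 2312 to 42615 ± 2177 normalized counts; reads may be shared among class I genes.

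Genes of immature mTEC rose in the libraries labelled Ko, with a median log2 fold change of 0.51 (14 tested, 11 positive; camera adjusted p = 0.00222; adjusted p = 0.368 with an estimated correlation), 1 member rising over all genes and 1 adjusted over the list alone. Without Ko2 the median was 0.24. The list's mean log2 level was highest in Ko1, at 9.96, with 9.61 and 9.02 in Ko2 and Ko3. In Het1, Het2 and Het3 it was 8.75, 8.45 and 8.38. The list's share of reads overlapped between the groups, and Ko3 was lowest. It was 0.179%, 0.166% and 0.177% in Het1, Het2 and Het3 and 0.238%, 0.269% and 0.151% in Ko1, Ko2 and Ko3. The mean log2 level of the fibroblast and mesenchyme list was highest in Ko2, at 8.26 against 5.67 to 6.75 in the other libraries. Ko1 was at 6.46 in that list. The called member was Lifr, the leukemia inhibitory factor receptor gene, at 1041 ± 290 in Het and 3409 ± 1036 in Ko libraries (limma adjusted p = 0.0328). The integrin gene Itgb4 was at 897 ± 150 and 1377 ± 175 (limma adjusted p = 0.303). Cortical epithelial genes were not called (14 tested, median -0.039, camera adjusted p = 0.853; 0 members called, 1 higher and 1 lower adjusted over the list alone), with the median negative and the test's direction upward. General thymic epithelial genes were not called (17 tested, median -0.057, camera adjusted p = 0.492); Krt19 fell from 11050 ± 2032 to 3945 ± 1711 (limma adjusted p = 0.0381), and 1 rose and 3 fell adjusted over the list alone.

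Cytosolic ribosomal protein genes rose by a small amount across the list, with 79 of 81 positive and a median log2 fold change of 0.34 (camera adjusted p = 9.37e-20; adjusted p = 0.289 with an estimated correlation), while 0 members were called, also adjusted over the list alone. Immediate-early and heat shock genes rose with a median of 0.15 (29 tested, 20 positive; camera adjusted p = 0.0338; adjusted p = 0.583 with an estimated correlation), with 0 members called, and 3 higher and 1 lower adjusted over the list alone. Their mean log2 level overlapped between groups, at 11.53 in Het1 against 11.45 and 11.49 in Ko2 and Ko3. The median was 0.39 without Het1 and 0.017 without Het2. Their call was lost without Het2 (adjusted p = 0.494), Ko1 (0.287) or Ko2 (0.0506), with genes of a mean of at least 50 (0.0802), and with TMM or quantile scaling. Over the alternatives the adjusted p ran from 1.17e-04 to 0.583. Among signalling and chromatin lists none was called: the Notch pathway (20 tested, median 0.29, camera adjusted p = 0.0562), the NF-kB pathway (22, -0.25, 0.0678), interferon-stimulated genes (36, 0.19, 0.134), the NuRD complex (15, 0.22, 0.182), the Ikaros family (5, 0.15, 0.182), cell cycle genes (32, 0.086, 0.462) and mitochondrially encoded genes (8, 0.17, 0.105). Within them the Notch ligand gene Jag2 rose from 799.5 ± 106 to 1981 ± 38.0 (SD, n = 3 each; limma adjusted p = 0.0341) and the immunity-related GTPase gene Igtp from 1276 ± 32.8 to 2742 ± 334 (0.0403). Adjusted over the list alone, 1 Notch, 2 interferon, 1 NuRD and 1 Ikaros family gene were higher, 1 interferon and 3 NF-kB genes were lower, and 0 cell cycle and mitochondrial genes were called.

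Markers of other cells that the sort could hold were not called as lists: thymocytes and T cells (19 tested, median -0.38, camera adjusted p = 0.703), B cells (11, 0.0050, 0.703), myeloid and dendritic cells (17, -0.86, 0.0912), innate lymphoid cells (9, -1.96, 0.256), fibroblasts and mesenchyme (18, 0.076, 0.804), endothelial cells (12, -0.099, 0.678), neurons and Schwann cells (12, -0.87, 0.569) and red blood cells (5, -3.84, 0.182). Cd79b, a B cell receptor component gene, rose from 2463 ± 581 to 5279 ± 538 normalized counts, and Id2 from 8657 ± 420 to 13904 ± 955 (SD, n = 3 each; limma adjusted p = 0.0433 and 0.0407). Cd79a was at 39.5 ± 59.4 and 1.51 ± 0.515. Stmn2 was the called member of the neuron list. The myeloid gene Lyz2 was at 21898 ± 27312 in Het and 1509 ± 1245 in Ko libraries (limma adjusted p = 0.122), and the haemoglobin gene Hbb-bs was at 293, 2.84 and 6292 in Het1, Het2 and Het3 and at 4.39 ± 3.35 in Ko libraries. Adjusted over the list alone, 1 T cell, 1 B cell, 1 innate lymphoid and 1 neuronal gene were higher, 1 innate lymphoid and 1 neuronal gene were lower, and 0 were called in the other 4 lists.

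**Figure D3:**
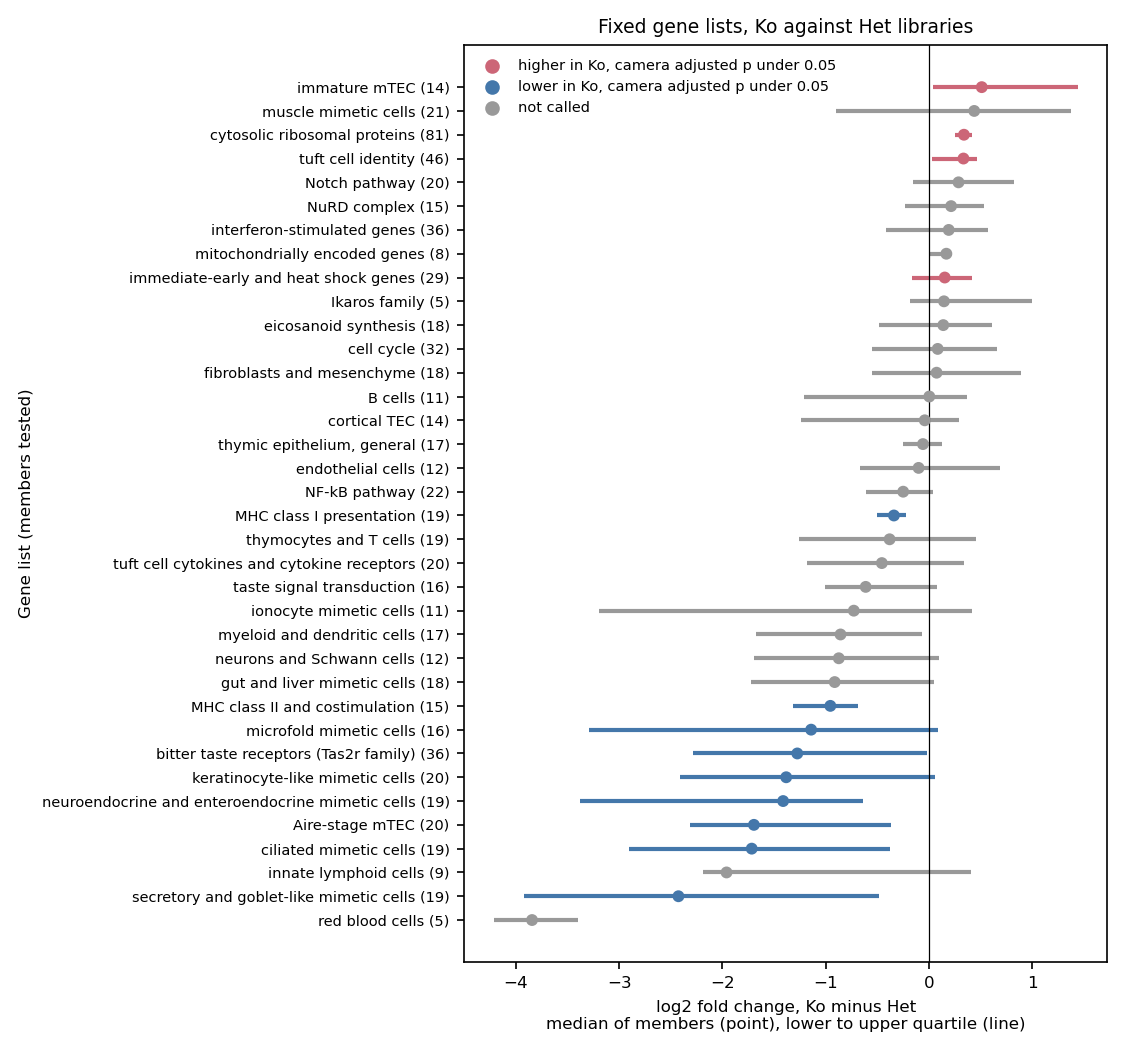
Median log2 fold change of the tested members of each of 36 gene lists, Ko minus Het, with lines from the lower to the upper quartile and the number of members in brackets. The 4 lists called higher and 9 called lower by camera are coloured. None of the 13 calls held in camera with an estimated correlation (lowest adjusted p = 0.172), a setting with few degrees of freedom. For MHC class I and microfold genes that correlation was -0.013 and -0.042, under the preset 0.01. Correlated genes therefore do not account for the loss of those calls.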

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

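The block by column number, the thinning and the list tests under other scalings were chosen after the data were seen. The number of genes called depended on the test and on single libraries. Genes higher in the libraries labelled Ko numbered 56 in limma, 37 with TMM scaling, 89 with robust eBayes, 24 in edgeR, 383 in DESeq2 and 20 in voom; genes lower numbered 102 in limma, 51 in edgeR, 768 in DESeq2 and 20 in voom. Leaving out 1 library gave 0 to 47 higher and 0 to 94 lower, with 0 in both directions without Het3; fewer samples are part of these settings, and the cause of the differences between tools was not tested. Under the other settings, apart from the replicate block below, the counts stayed within 1.5 times. All 158 genes kept their direction in all 21 alternatives. Their groups did not overlap, so leaving out 1 library could not turn a direction. Of the 158, 75 were called by edgeR, 158 by DESeq2 and 39 by voom. The median log2 fold change of all genes was -0.051 and moved by 0.13 with quantile normalization. Ikzf1 kept its direction throughout (log2 fold change 2.46 to 2.80 with 1 library left out) and its side of the threshold except without Het3 (adjusted p = 0.0621, in a range of 3.16e-14 to 0.0621). No paired analysis was possible because the columns carry no title number, although the titles number the samples in adjacent pairs of a Cre-negative and a Cre-positive sample; a replicate block by column number, which need not follow those pairs, with correlations of deviations of 0.025, 0.021 and -0.015, gave 25 higher and 62 lower. The planned term for the range of title numbers was not run for the same reason. Camera's 4 lists higher and 9 lower became 0 and 0 with an estimated correlation and 2 and 2 with fry (ribosomal proteins and the Notch pathway, the latter not called by camera, higher; MHC class I and microfold genes lower), which does not compare a list with other genes; in the other settings, 3 to 5 and 7 to 10 were called. Reversals concern results that were not called: Ikzf2 (-0.47 to 0.16 with 1 library left out, positive without Het1), and lists whose camera direction turned, with the range of their medians: cortical epithelium (-0.34 to 0.21; -0.039 with fry), endothelium (-0.20 to 0.10), fibroblasts (-0.68 to 0.31; 0.076 with fry), muscle (-0.45 to 1.23) and T cells (-0.62 to -0.15); the cause was not tested. Medians of the cell cycle, cortical, B cell, fibroblast and endothelial lists changed sign with a scaling. Depth limits genes under about 4 normalized counts, which is 3 reads in Het3 or Ko3.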

Other observations

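In all, 11 gene families taken by symbol were looked at after the data were seen, some because of members among the changed genes, so their counts are descriptions and no family test is given. All 22 tested kallikrein genes (Klk) had negative fold changes in the libraries labelled Ko, with a median log2 fold change of -5.31 and 4 called lower by limma. All 9 Sprr genes of the cornified envelope were negative as well, median -3.11, with 3 called lower. Sprr1a fell from 17670 ± 3610 to 2779 ± 1113 normalized counts and Rptn, encoding repetin, from 5101 ± 1616 to 236 ± 135 (SD, n = 3 each; limma adjusted p = 0.00978 and 0.00585). Of 12 S100a genes 10 were negative (median -0.93), with S100a9 called lower, and of 39 keratin genes 31 were negative (median -0.69). Near-identical members of the Klk and Sprr families can share reads. The directions held under all 3 other scalings.

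Some ion channel genes went the other way. The potassium channel genes Kcnh7, from 498 ± 96.6 to 2190 ± 473, and Kcnq3, from 1136 ± 181 to 2943 ± 148, rose in the libraries labelled Ko (limma adjusted p = 0.0122 and 0.0226), as did the calcium channel gene Cacna1d, from 376 ± 40.0 to 1225 ± 251 (0.0381). Of the 55 tested potassium channel genes, 32 had a positive fold change (median 0.19). Cd44, an adhesion receptor gene, rose from 3712 ± 910 to 10426 ± 480 and Sema5a from 1126 ± 301 to 3850 ± 171 (limma adjusted p = 0.0122 for each). These genes were chosen after their values were seen.

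All tests of the explanations below were chosen after the result was seen, except the counts over other splits. The first pattern is the higher Ikzf1 in the libraries labelled Ko. Lymphoid or myeloid cells would bring their other transcripts along, yet the 47 tested T cell, B cell and myeloid genes had a median log2 fold change of -0.47. Their upper quartile was 0.34, against 2.66 for Ikzf1. Pooling could hide a source of 1 kind, but the upper quartile was 0.46 for T cell, 0.37 for B cell and -0.069 for myeloid genes alone. For innate lymphoid genes, which are outside the 47, it was 0.41. Among these lists Cd79b and Id2 were called higher, and B cell genes took a larger share of reads in the Ko libraries. Cst3 and Cd79b, 2 of the most abundant of the 47 genes, stood at 15304 and 2463 in Het and 18291 and 5279 in Ko libraries. Lyz2, also among them, was at 53299.9, 3666 and 8729 in Het1, Het2 and Het3, so that its Het mean rests on Het1, and at 497, 2900 and 1130 in Ko1, Ko2 and Ko3; such cells would also have to pass the L1CAM sort. If 1 or 2 library names were exchanged between the groups and Ikzf1 followed the genotype, libraries would lie in the other group's Ikzf1 range. Their number was 0, which argues against such an exchange, but these values are the pattern itself and no independent value was used. An exchange of the names of both whole groups cannot be told apart from a true rise by these tables (log2 fold change 2.66), because no value other than Ikzf1 marks the genotype. A transcript of the recombined allele that is still counted over the rest of the gene may also be involved; exon counts were not used here, so this was not tested.

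The second pattern is the fall of the secretory and goblet-like list. A larger share of all other thymic cells in the Het libraries would lower the lists of such cells in Ko libraries. It need not lower them equally, since some members, such as Spib and Rac2 in the microfold list, are also in the tuft cell list. Unequal falls of the lists therefore do not decide the question. Of 18 other cell lists, 14 also had a negative change of the mean log2 level, with a mean change of -0.97 ± 0.20 over the 18 (SE over libraries). The largest of these falls, of red blood cell genes (-3.30 ± 2.03), rested on Het3, at a mean log2 level of 10.75 against 4.81 and 4.53 in Het1 and Het2. The secretory list (-2.35 ± 0.63) lay below that mean by 1.38 ± 0.56, which passes 2 SE but not the 2.78 SE of a two-sided 95% bound, and it was picked as a large change, so this explanation cannot be told apart from a change of the secretory program. The lists did not all move alike, since immature mTEC rose by 1.005 ± 0.30 while microfold (-1.74), neuroendocrine (-1.83), ciliated (-1.72), keratinocyte-like (-1.70) and Aire-stage genes (-1.69) fell, and cortical epithelium (-0.43 ± 0.23), endothelium (0.016 ± 0.49), fibroblasts (0.093 ± 0.77) and muscle (0.26 ± 0.87) moved little or with a wide spread. The authors' scaling is argued against by the list's median of at most -2.40 under 3 other scalings, and depth by a median of -2.38 after all libraries were thinned to the same number of reads. Other thymic or mimetic cells would have to pass the L1CAM sort. Fewer secretory mimetic cells among the sorted cells, lower expression within tuft cells and the genotype as labelled were not tested and remain open.

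The third pattern is the rise of Fxyd7, Gabrg3, Hoxa2 and Fcna from close to undetected, and of Stmn2 from a low level. Neurons or Schwann cells in the Ko libraries are argued against by the other 11 tested neuronal genes, whose median log2 fold change was -1.22 and upper quartile -0.00475, against at least 4.78 for the 5 genes; Mbp, the most abundant, was at 623 in Het and 565 in Ko libraries. Depth is argued against by fewer reads in the Ko libraries, with a ratio of Ko to Het reads of 0.668. No other cell type was tested as a source, nor was a change within tuft cells, so both remain open.

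The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 158 genes by limma and the highest of the others 0 (556 to 1198 genes with an unadjusted p under 0.05, 0 by edgeR, up to 190 by DESeq2), so that 1 of 10 splits reached the real count. For lists the real split gave 13 and the highest of the others 12, so that again 1 split reached the real count. The 3 splits that put Het1 with 2 Ko libraries called 12, 10 and 7 lists, and the other 6 called 3 to 6. Each of these 9 splits exchanges 1 library of each group and so keeps part of the difference between the groups.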
